A study of Mus musculus with 6 samples.

How the data were processed

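Allele-specific mRNA sequencing was done on female F1 mouse placenta from reciprocal crosses, named with the mother before the father. There were 6 libraries, 1 per group: AKRxPWD and PWDxAKR at embryonic day 17.5, B6xCAST and CASTxB6 at embryonic day 17.5, and B6xCAST and CASTxB6 at embryonic day 13.5. Per the labels' protocols, libraries were made with a TruSeq kit from 4 µg of RNA, pooled, and sequenced as 51 bp reads on 3 lanes. All 6 libraries were pooled over the same lanes, so lanes do not separate the groups.

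The deposited files list, per single-nucleotide polymorphism (SNP) in an exon or untranslated region, the expected count of reads from each parental strain, with gene identifiers, per the file headers. About 15% of these counts are not whole numbers, and the reason is not given in the sources used here. Per the submitters' processing notes, TopHat and genome build mm9 were used. The tool's version and role, and whether strand was used in counting, are not given in the sources used here, so reads of overlapping and antisense genes could not be told apart. The reference genome at hand was of another build and was not used for coordinates. All positions are those of the files (mm9) and give the span of a gene's SNPs.

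The files list only SNPs covered by at least 8 reads, with 1 library reaching down to 6. They hold 81186 SNPs for AKR/PWD, 79281 for B6/CAST at embryonic day 17.5 and 83061 at embryonic day 13.5, in 10987 genes, 7756 of them in all 3 pairs. Small shares of the allele that differs from the reference genome were mostly listed at 0. Among 13447 SNP values with at least 300 reads, the non-reference base was at 0 in 512, above 0 but under 2% in 2 and between 2% and 5% in 15. For the reference base these numbers were 5, 212 and 187. A share of 100% or 0% in these data can therefore hide a few percent of the CAST allele, or of the PWD allele at the 87.0% of AKR/PWD SNPs where AKR carried the reference base.

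Within each gene, SNPs were thinned to at least 51 bp apart, taking the best covered SNP first, so that a read was counted once. Allele counts were summed per gene and rounded to whole numbers. Thinning left 4340948 to 5233324 allele reads per library. Genes with at least 20 informative reads in each library were tested, which gave 6857 genes, 6652 autosomal and 205 X-linked.

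Parent and strain effects were tested in 1 fit with edgeR 4.0.16 (quasi-likelihood test) in R 4.3.3. Its 12 columns were the maternal and paternal allele of each library, with terms for library, for AKR over PWD, for B6 over CAST and for mother over father, and with the same library size for both alleles. Each group held 1 library, so all groups shared 1 estimate of the spread, with 3 residual degrees of freedom per gene. A second fit with a parent term per pair tested the difference in parental bias between stages and between strain pairs. The stage comparison used gene totals over the 70046 SNPs common to both B6/CAST pairs, 2 libraries against 2, with TMM scaling and edgeR's filter on low counts, which left 8685 genes. It covers genes listed at both stages. P-values were adjusted with the Benjamini-Hochberg method and the threshold was 0.05. Standard errors (SE) were the log2 effect divided by the square root of the F statistic. The labels do not say how many placentas or litters a library came from, so p-values measure only the spread between these libraries.

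Shares of single libraries are given with exact Clopper-Pearson 95% intervals, which cover counting error only. A rule of size without a test was applied within each pair: at least 70% of reads from the same parent in both libraries. The X-linked share was the median over genes per library, set against 50% with an exact two-sided sign-flip permutation over 6 libraries. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, and again with an estimated correlation. The 17 lists were imprinted genes known to be paternally or maternally expressed, genes reported as maternal in placenta with decidua as a suspected source, decidual stroma, uterine natural killer cells and maternal leukocytes, spongiotrophoblast, trophoblast giant cells, labyrinth, fetal endothelium, yolk sac, embryonic globins, erythroid genes, cell cycle, extracellular matrix, hypoxia and glycolysis, interferon response, and genes that escape X inactivation. Lists with under 3 tested members were not tested, and X-linked members were left out of the parental tests.

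Groups, designs, lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule took the 10 autosomal genes with the largest and the 10 with the smallest maternal over paternal effect among those past the threshold with the same direction in all libraries, together with measured members of the known imprinted lists. It also took Xist, the escape list and the 5 X-linked genes of lowest maternal share, the 5 largest strain effects on each side, up to 8 genes per pair by reads for the rule of size, the 10 largest stage changes on each side without overlap, and up to 4 list members by reads plus those past the threshold. The strain genes named with autosomal position and no parental bias, the genes named for differences in bias between pairs, and any other gene were chosen after their values were seen. CPM are counts scaled to the TMM-adjusted library size.

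Alternatives were all SNPs summed, other read minima, removal of SNPs with a possibly wrong genotype, TMM or median-of-ratios scaling per allele column, DESeq2 1.42.0, B6/CAST libraries only, each library left out, other sizes for the rule of size, and, for stage, other scaling, no filter and a term for cross direction. Setting the non-reference alleles listed at 0 to 2% of coverage, using only the 4 libraries of embryonic day 17.5, and counting strain differences without X-linked and parentally biased genes were added after seeing the data. The fits for parent, B6/CAST strain, parent by stage and stage were tested on simulated counts with 200 changed genes. The AKR/PWD strain term and parent by cross were not. Apart from the changed genes no effects were simulated, the spread followed its trend over expression, and no small non-reference shares were set to 0. The rates below may therefore be better than in the data. For parent of origin, over 6857 genes, 88% of genes changed 1.5-fold and 100% of those changed 2-fold or more were recovered, with 4 false calls. For the B6/CAST strain term 98.5% of 2-fold changes were recovered, with 15 false calls. For parent by stage 96% of 4-fold changes were recovered, with 13 false calls. For stage, over 8685 genes, 50.7% of 2-fold, 95.5% of 4-fold and 100% of 8-fold changes were recovered, with 17 false calls. Tables and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.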

Results

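Allelic expression was measured in 6 placental libraries from reciprocal crosses of AKR with PWD and of B6 with CAST, where the parental alleles of a gene are told apart by SNPs. Reciprocal crosses separate the effect of the parent from that of the strain, since each strain is the mother in 1 library and the father in the other. Every group held 1 library. The libraries held 6077445 allele reads for AKRxPWD, 5445126 for PWDxAKR, 6362984 and 6716694 for B6xCAST and CASTxB6 at embryonic day (E) 17.5, and 6243096 and 6109013 for B6xCAST and CASTxB6 at E13.5. Over autosomal genes the maternal share of reads lay between 49.1% and 51.1% in each library.

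The first comparison was of the maternal with the paternal allele of autosomal genes. Cdkn1c, an inhibitor of cyclin-dependent kinases (chromosome 7, 150644367 to 150644763, mm9), was read almost only from the maternal allele, at 99.0% ± 1.25 (SD, n = 6). H19, a long non-coding RNA next to Igf2, had a maternal share of 98.9% ± 0.807, the zinc finger gene Zim1 98.9% ± 1.06, and Igf2r, the receptor that clears Igf2, 97.1% ± 3.30. On chromosome 12 the non-coding RNAs Meg3, Rian and Mirg stood at 98.5% ± 1.82, 98.2% ± 2.54 and 97.2% ± 3.29, and 3 SNORD113 small nucleolar RNA entries of the same chromosome at 97.2% to 98.4%. The SNPs of these entries, for 1 of them at 110894104 to 110895023, lie between those of Rian and Mirg. Their reads may be of a longer transcript, so the shares cannot be given to the small nucleolar RNAs themselves. Igf2, a fetal growth factor (chromosome 7, 149836880 to 149840221), was read from the paternal allele in all libraries, with a maternal share of 0.533% ± 0.607 over 5552 to 20793 reads per library.

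Other paternally read genes were Mest, a hydrolase-like gene, with a maternal share of 0.0502% ± 0.123, the entry mmu-mir-431 with 0.481% ± 0.976 and Dlk1, a transmembrane regulator of differentiation, with 0.634% ± 0.873. The antisense entry Igf2as stood at 1.77% ± 2.40, Peg10, a retrotransposon-derived gene needed for placental growth, at 2.11% ± 4.50, and the splicing factor relative Zrsr1 at 2.85% ± 5.42. Usp29, a ubiquitin peptidase gene, stood at 3.65% ± 4.74, its neighbour Peg3, a zinc finger gene, at 4.61% ± 5.83, and the amino acid transporter Slc38a4 at 6.61% ± 9.35. Reads per library were few for Zrsr1 (28 to 62), Usp29 (35 to 112) and, in B6/CAST, Mest (32 to 40). Maternal shares of several percent can be missed there. Of 6652 autosomal genes, 37 were higher from the maternal allele and 22 from the paternal allele in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The adjustment ran over all 6857 tested genes, 205 of them X-linked. Most X-linked genes passed, so 0.05 is not the rate of false calls among the autosomal genes alone. The bias had the same direction in all 6 libraries for 29 of the maternal and 20 of the paternal genes, and it was at least 2-fold for 18 and 21. Adjusted p-values (edgeR) of the genes named so far ran from 2.03e-08 for Igf2 to 0.00375 for Peg10. The strand of the reads is not known. Igf2as lies beside Igf2, and the SNPs of mmu-mir-431 (110828154 to 110828360) lie within the span of Rtl1 (110827463 to 110832889), also read from the father, so neither share can be given to the entry itself. Shares near 0% or 100% can miss a few percent of the CAST or PWD allele.

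**Figure D1:**
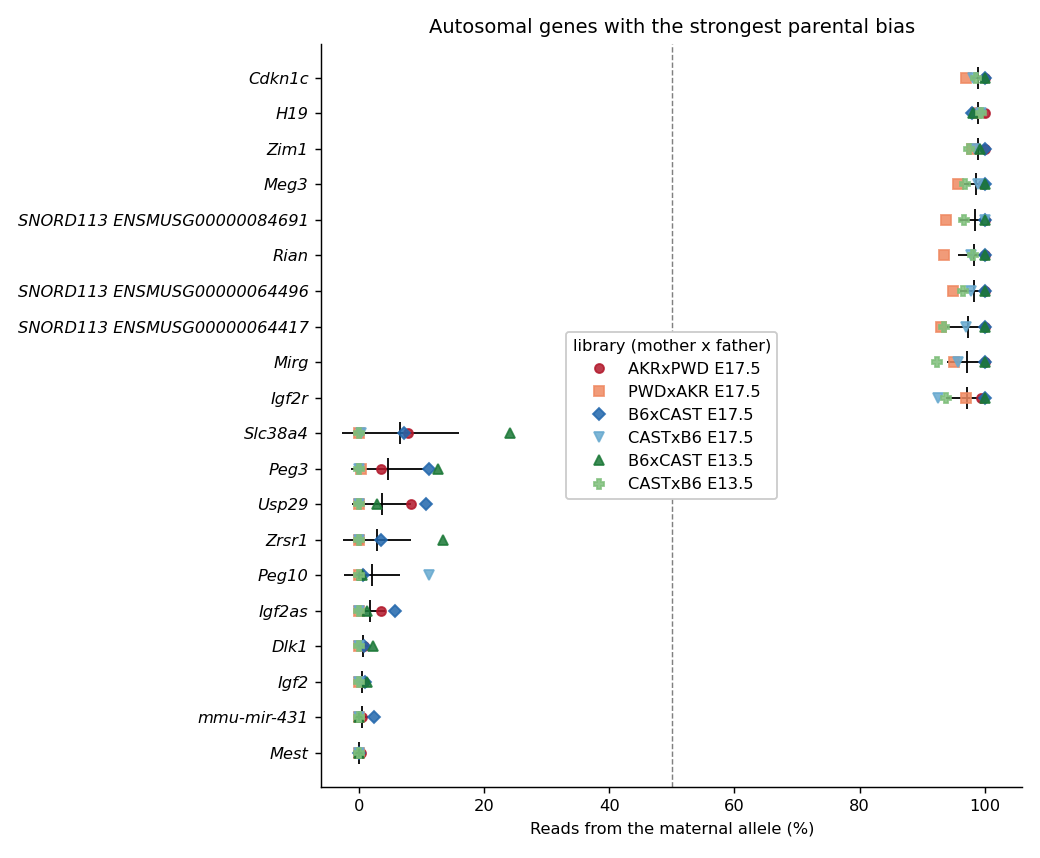
Maternal share of reads (percent, x axis) of the 20 autosomal genes with the strongest parental bias, with 1 symbol per library and a black bar for the mean with its SD (n = 6). The maternal genes lie above 92% in each library, and the highest single value among the paternal genes is 24.1%, for Slc38a4 in B6xCAST at E13.5.

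Members of the known imprinted lists followed the parent named by the list in most cases. Of 19 measured paternally expressed genes 17 were higher from the father, also when adjusted over the list alone. Examples are the transcription factor Plagl1 at 2.24% ± 0.761 maternal reads, the chromatin gene Sfmbt2 at 3.18% ± 2.07, the retrotransposon-derived Rtl1 at 4.48% ± 3.18, and the sarcoglycan gene Sgce at 9.17% ± 4.28 (SD, n = 6 each). Impact (13.6% ± 10.6), Zdbf2 (19.8% ± 6.38), the signalling adaptor Gab1 (26.9% ± 6.15), Smoc1 (28.5% ± 8.90) and Phf17 (32.6% ± 8.25) kept a larger maternal part. Inpp5f (51.2% ± 4.43) and Zfp787 (54.0% ± 4.48) did not pass the test. Without either AKR/PWD library Phf17 no longer passed, at a log2 maternal over paternal of -0.88.

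Of 18 measured maternally expressed genes 11 were higher from the mother, and 13 when adjusted over the list alone. Besides those above they included the transporter Slc22a18 at 87.3% ± 8.87, the growth inhibitor Grb10 at 78.2% ± 7.95, the peptidase H13 at 65.5% ± 2.42, and Gnas, a G protein subunit, at 57.8% ± 4.55. Ano1, a chloride channel, stood at 72.2% ± 11.4 with an adjusted p of 0.0529 (edgeR) and was maternal in 6 of 6 libraries. It passed the test without either AKR/PWD library, at a log2 of 1.95. Trappc9 (55.2% ± 4.49), Commd1 (51.9% ± 6.53), Blcap (49.1% ± 3.96), Ube3a (49.0% ± 4.37) and Zfat (48.0% ± 4.78) did not pass. Copg2, listed as maternal, was higher from the father in the B6/CAST pairs, with 4.89% to 9.12% maternal reads, and stood at 47.5% and 53.5% in AKR/PWD. The paternal excess of Copg2 came from SNPs at chromosome 6, 30697590 and 30697834, next to Mest and scored only in B6/CAST, which were 97.4% to 100% paternal. At 30760424 and 30760463, also scored in AKR/PWD, paternal reads were 32.8% to 44.4% in the B6/CAST libraries.

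Weaker maternal bias was called for some genes near imprinted genes, 16 of 483 other tested autosomal genes within 5 Mb of a called one. On chromosome 17 around Igf2r, the phosphodiesterase Pde10a stood at 86.7% ± 6.39 maternal reads, the cation transporter Slc22a3 at 85.3% ± 7.37 and the matrix protein gene Thbs2 at 78.4% ± 14.7. The RNA-binding protein gene Qk followed at 58.4% ± 1.52, Mllt4 at 56.7% ± 3.58, Agpat4 at 56.2% ± 14.5 and Map3k4 at 55.8% ± 2.73 (SD, n = 6). Beside Peg10 on chromosome 6, Ppp1r9a, a neuronal scaffold gene, stood at 78.0% ± 9.29, Casd1 at 59.2% ± 5.51, and the paraoxonase Pon2 at 61.0% ± 37.8, with B6 reads well above CAST reads. Klhdc10 near Mest stood at 64.3% ± 3.88, and Nap1l4 near Slc22a18 at 55.9% ± 3.74. Around Plagl1 on chromosome 10, Phactr2 stood at 65.7% ± 6.22, Ltv1 at 60.5% ± 5.15 and Fuca2 at 56.6% ± 18.4. Itih5 near Sfmbt2 stood at 54.4% ± 19.5.

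Farther from known imprinted genes, the chromatin remodelling gene Arid1b had 62.8% ± 1.79 maternal reads, the Polycomb gene Cbx7 61.9% ± 16.4, the angiopoietin gene Angpt2 60.2% ± 18.7, Ctla2a 59.8% ± 14.2 and catalase (Cat) 56.1% ± 15.7 (SD, n = 6). Hbb-b2 stood at 65.0% ± 12.8, but it is a near copy of Hbb-b1 and its reads are uncertain. Zfp64 (31.4% ± 11.2) and E130012A19Rik (40.3% ± 8.38) were higher from the father. The genes of these regions were chosen as all those past the threshold that the rule had not named. Cat, Angpt2 and Itih5 were maternal in 3 of 6 libraries, Pon2, Cbx7, Ctla2a and Agpat4 in 4, since strain effects moved their shares to either side. Without AKRxPWD 49 of the 59 genes remained, and without PWDxAKR 49. The genes lost were Agpat4, Cat, Fuca2, Hbb-b2, Itih5, Map3k4, Mllt4, Nap1l4, Phf17 and Pon2 in both cases, while Angpt2 and Ctla2a were lost without other single libraries. The fits without AKRxPWD and without PWDxAKR are not independent. The AKR/PWD library left is taken up by its strain term, so their parent term comes from the 4 B6/CAST libraries.

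**Figure D2:**
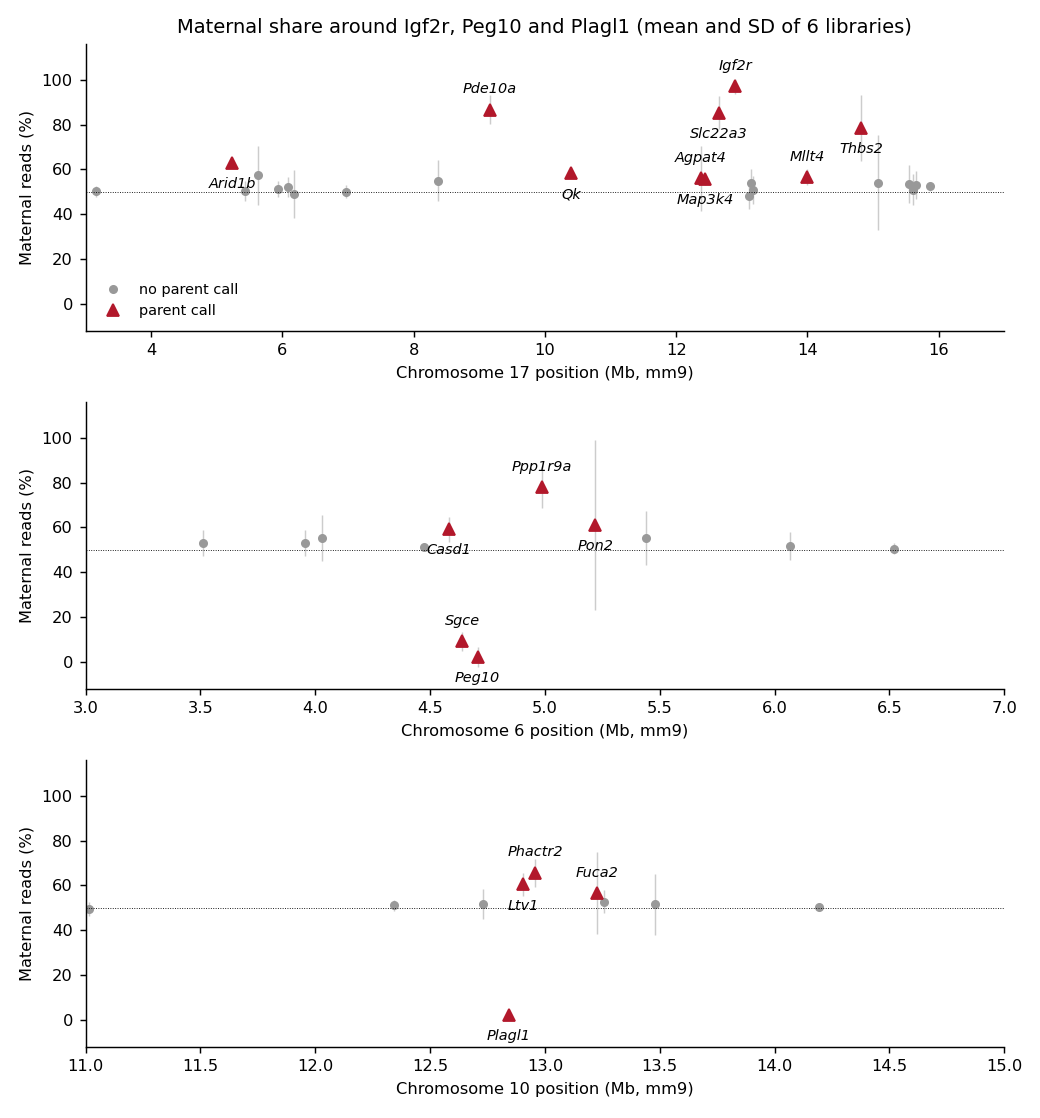
Maternal share of reads (percent, y axis, mean with SD of 6 libraries) against position (Mb, mm9) of tested genes around Igf2r, Peg10 and Plagl1, with red triangles for genes past the test for parent of origin and grey circles for others. On chromosome 17 the triangles run from Arid1b at 62.8% over Igf2r at 97.1% to Thbs2 at 78.4%.

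Among the gene lists fixed beforehand, 5 of 13 stood apart for parent of origin by camera, and all 5 also did with an estimated correlation. The known paternal list had a median log2 of -5.31 (adjusted p = 0.000795 with an estimated correlation) and the known maternal list 1.5 (adjusted p = 0.000795 with an estimated correlation). Genes reported as maternal in placenta, with decidua as a suspected source, had 6 of 7 tested members higher from the mother, also adjusted over the list alone (adjusted p = 0.0324 with an estimated correlation). These were Pde10a, Slc22a3, Ppp1r9a, Pon2, Casd1 and Nap1l4, while the matrix proteoglycan Dcn stood at 59.6% ± 15.3. The spongiotrophoblast list tested up with 1 of 10 members past the threshold, Cdkn1c, although its median log2 was -0.02 (adjusted p = 0.0218 with an estimated correlation). The labyrinth list tested down with 2 of 15, Igf2 and Slc38a4, although its median log2 was 0.000634 (adjusted p = 0.0218 with an estimated correlation). Those counts were the same adjusted over the list alone.

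The other lists did not pass by camera. Decidual stroma had 1 of 9 past the threshold, Angpt2, and 2 adjusted over the list alone, with the muscle filament gene Des at 70.4% ± 17.1 and the smooth muscle actin Acta2 at 49.9% ± 4.68 maternal reads (SD, n = 6). Fetal endothelium (11 genes), yolk sac (11), trophoblast giant cells (7), cell cycle (4), extracellular matrix (21), hypoxia and glycolysis (10) and interferon response (9) had 0 past edgeR's threshold over all genes and 0 adjusted over the list alone. The endothelial median log2 was 0.00423 while the test pointed down. Examples are the endothelial cadherin Cdh5 at 50.5% ± 1.81, the yolk sac protein Afp at 50.1% ± 1.46, the placental lactogen Prl3b1 at 50% ± 4.13 and fibronectin (Fn1) at 50.4% ± 3.73.

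X-linked genes were read mainly from the maternal X, and female mouse placenta is known to silence the paternal X. The median maternal share over 205 X-linked genes was 99.3% in AKRxPWD, 94.1% in PWDxAKR, 96.2% and 96.9% in B6xCAST and CASTxB6 at E17.5, and 97.8% and 96.4% at E13.5. Their mean was 96.8% ± 1.74 (SD, n = 6, exact two-sided sign-flip p = 0.0312, the smallest this design allows), against 50.2% ± 0.41 for autosomal genes. In edgeR's test 195 genes were higher from the mother, and Xist, the RNA that coats the silent X, was the 1 gene higher from the father, at 3.22% ± 3.15 maternal reads.

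Genes known to escape X inactivation kept a paternal part of varying size. The histone demethylases Kdm5c and Kdm6a stood at 73.5% ± 4.82 and 80.3% ± 8.13 maternal reads (SD, n = 6), Utp14a at 79.8% ± 12.3 and the RNA helicase Ddx3x at 92.6% ± 4.17. Shroom4 (96.4% ± 2.91) and Car5b (99.6% ± 0.721) had little. 1810030O07Rik (95.2% ± 5.36) stood at 100% where the father was PWD or CAST, whose small shares are mostly listed at 0. With AKR or B6 fathers it stood at 88.2% to 91.7%. The enzyme gene Ogt, chosen after its values were seen, stood at 61.8% ± 1.93 in all libraries alike. The 9 X-linked genes that passed in neither direction were Bgn, Kctd12b, Cxx1a, Ace2, Fhl1, 4930502E18Rik, Fndc3c1, Sh3bgrl and Alas2. Bgn, a matrix proteoglycan, stood at 49.4% ± 24.1, Kctd12b at 50.2% ± 28, Cxx1a at 53.5% ± 25.8, the peptidase Ace2 at 53.5% ± 24.7 and Fhl1 at 56.1% ± 18.0. Sh3bgrl stood at 60.1% ± 20.3. Without either AKR/PWD library 4930502E18Rik passed toward the mother (log2 0.74). In B6/CAST 8 of the 9 passed edgeR's test toward CAST, with 75.6% ± 6.58 CAST reads for Bgn (SD, n = 4), while Fndc3c1 had 44.2% ± 19.8.

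**Figure D3:**
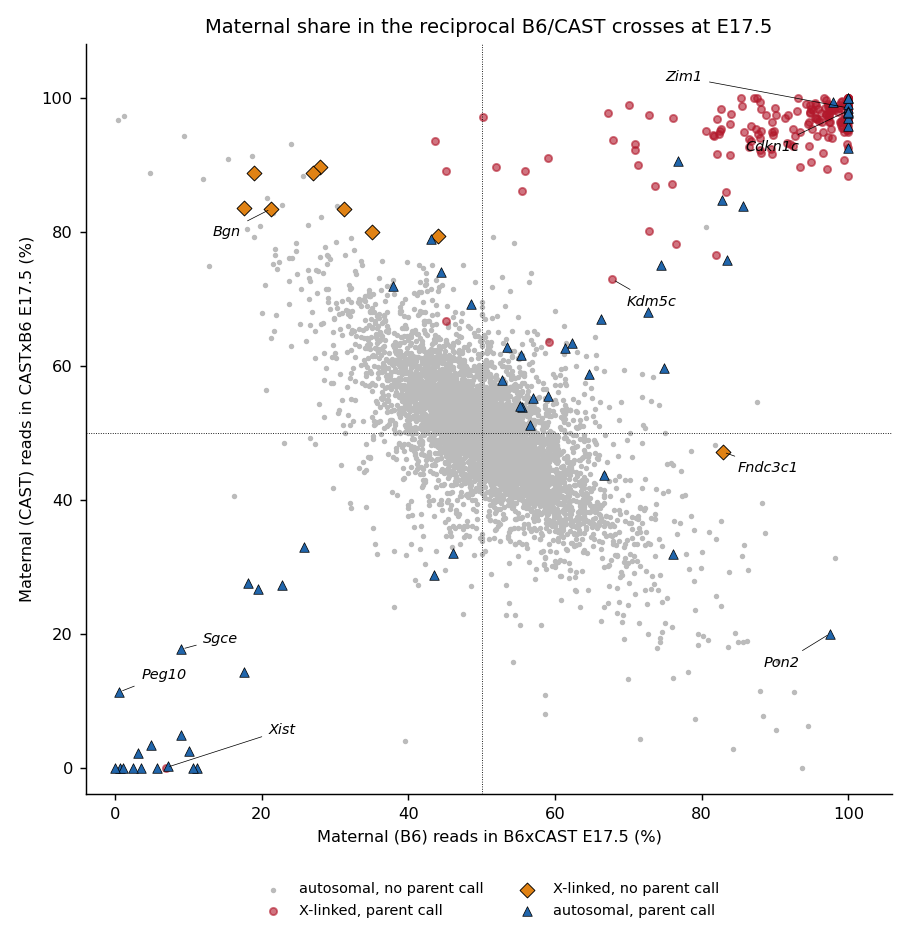
Maternal share of reads (percent) per gene in B6xCAST (x axis) against CASTxB6 (y axis) at E17.5. Autosomal genes without a parental bias (grey) spread along the falling diagonal, most autosomal (blue triangles) and X-linked (red circles) genes with a parental bias lie along the rising one, and 8 of the 9 X-linked genes without one (orange diamonds) lie on the CAST side.

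The strain comparison asked which genes were read more from 1 strain whichever parent carried it. In B6/CAST, Mx2, an interferon-induced GTPase, had 7.59% ± 2.69 B6 reads (SD, n = 4), the angiopoietin gene Angpt4 8.63% ± 5.05 and the neurotrophic receptor gene Gfra3 12% ± 6.10, so all were higher from CAST. The unnamed transcripts AC090123.2 and AC108773.2 stood at 2.17% ± 1.40 and 4.81% ± 3.62 B6 reads, the latter over 1 SNP. Pon2 was higher from B6, at 91.6% ± 9.08, as were the circadian deadenylase Ccrn4l at 90.5% ± 12.8, the surface protein gene Tm4sf1 at 93.6% ± 4.71, the serpin Serpinb9d at 92.1% ± 3.75, Rinl at 91.9% ± 3.02 and Dkkl1 at 88.9% ± 9.97. Serpinb9d has near copies in the genome and is uncertain. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 1031 genes were higher from B6 and 867 from CAST. Adjusted p of the named genes ran from 1.4e-05 (AC090123.2) to 0.00227 (Ccrn4l). Igf2, Peg3, Rhox6 and Rhox9, which are read from 1 parent, also passed toward B6. With the CAST shares listed at 0 set to 2% of coverage, Igf2 passed toward CAST (log2 B6 over CAST -0.40, adjusted p 0.0106), Rhox6 (-0.16) and Rhox9 (-0.11) did not pass, and Peg3 still passed toward B6 at 1.38 in place of 4.26. DESeq2 called 1206 genes in place of 1898. Without CASTxB6 at E17.5 there were 1195, and without CASTxB6 at E13.5 1253.

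In AKR/PWD, AC090123.2, Mx2, Angpt4 and Gfra3 were again among the largest effects, with 4.95% ± 0.935, 11.6% ± 16.4, 12% ± 5.63 and 14.1% ± 3.01 AKR reads (SD, n = 2). Chchd2, a mitochondrial protein gene, stood at 14.7% ± 5.47. The prolactin family gene Prl8a6 was higher from AKR, at 86.5% ± 8.94, as were the axon guidance gene Slit1 at 88.7% ± 0.325, Nedd9 at 93.1% ± 9.75, Tor3a at 87.7% ± 2.79 and Pik3r4 at 97.5% ± 3.54. Pik3r4 had 20 reads per library, Nedd9 22 and 29, Tor3a 21 and 29, and Chchd2 43 and 46. Each of these genes rested on 1 SNP, so a wrong genotype cannot be told from a strain effect. In edgeR's test 589 genes were higher from AKR and 339 from PWD. The X-linked genes Zfp36l3, Pdha1, 4933402E13Rik and Htatsf1 passed toward AKR and are read from the maternal X. With the PWD shares listed at 0 set to 2% of coverage, Zfp36l3 (log2 1.41), 4933402E13Rik (0.24) and Htatsf1 (0.41) no longer passed, while Pdha1 did (1.08 in place of 4.98). Only these 2 libraries carry the term, with the spread taken from all 6. DESeq2 called 510 genes, without Zfp36l3 (log2 3.23). There were 46 calls without AKRxPWD, 44 of them shared with the full fit, and 48 without PWDxAKR, 43 of them shared. Without AKRxPWD Angpt4 (log2 -3.19), Gfra3 (-2.33), Chchd2 (-2.59), Nedd9 (2.59), Slit1 (3.21) and Tor3a (2.77) no longer passed. Without PWDxAKR this held for AC090123.2 (-2.91), Mx2 (-2.21), Angpt4 (-2.68), Gfra3 (-2.92), Chchd2 (-2.53), Pik3r4 (4.13), Tor3a (2.83), Pdha1 (4.08), 4933402E13Rik (4.07) and Htatsf1 (3.95), and Zfp36l3 turned (-0.52). Prl8a6 passed in both cases. Of 6593 autosomal genes without parental bias, 441 were called in both strain pairs, against 233.4 for independent lists. Of these, 354 lay on the same side (118.6 for independent lists) and 87 on opposite sides (114.8). On the same side were 211 for AKR with B6 and 143 for PWD with CAST. Loss of reads with the non-reference base would raise the first number, since AKR carried the reference base at 87.0% of SNPs. The numbers for independent lists take no account of read depth.

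Parental bias was then compared between stages and between strain pairs. Huwe1, an X-linked ubiquitin ligase, had 99.6% and 88.5% maternal reads in AKRxPWD and PWDxAKR and 71.4% and 90% in B6xCAST and CASTxB6 at E17.5, a difference of 3.15 ± 0.23 (log2, SE) between the strain pairs. With PWD or CAST mothers the shares were close, so this difference rests on AKRxPWD and B6xCAST. In AKRxPWD small shares of the paternal PWD allele can be listed at 0, so the size of the difference is uncertain. Copg2 differed by 3.82 ± 0.29, which rests on the SNPs beside Mest scored only in B6/CAST. At its SNPs scored in both pairs (30760424 and 30760463) paternal reads were 32.8% to 43.2% in B6/CAST at E17.5 and 38.4% to 60.5% in AKR/PWD. H19 had 100% and 98.6% maternal reads in AKR/PWD against 98.0% and 99.4%, and the size of its difference is not known because its paternal PWD allele is listed at 0 in AKRxPWD. None passed in edgeR's test with Benjamini-Hochberg adjustment, with adjusted p of 0.0746 for Huwe1 and Copg2 and 0.126 for H19. The number of genes whose bias differed between strain pairs was 0 by edgeR, with 121 at an unadjusted p under 0.05, and 3 by DESeq2. The 3 genes, Huwe1, Copg2 and H19, also passed in edgeR with all SNPs summed or with median-of-ratios scaling, and Huwe1 and Copg2 with TMM. Between E17.5 and E13.5 in B6/CAST, 0 genes differed by edgeR, with 109 at an unadjusted p under 0.05, and 0 by DESeq2, with 24. Grb10, for example, had 74.4% and 75.0% maternal reads at E17.5 and 88.0% and 88.5% at E13.5. Genes for both comparisons were chosen after their values were seen.

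Within single pairs, genes that the joint fit could not test were listed by size. In AKR/PWD the paternal Peg13 stood at 98.9% (95% Clopper-Pearson interval 97.6 to 99.6) and 99.6% (98.7 to 100) paternal reads, and the neuronal proteolipid gene Nnat at 95.2% (90.8 to 97.9) and 100% (97.8 to 100). The non-coding Airn, which lies antisense to Igf2r, stood at 94.9% (87.4 to 98.6) and 100% paternal, the splicing gene Snrpn at 98.4% (91.2 to 100) and 91.4% (81.0 to 97.1), and D7Ertd715e at 100% in both. Maternal were Klf14, a transcription factor, at 100% and 98.3% (94.1 to 99.8), and the small nucleolar RNA entries SNORD113 (100% and 96.2%, the latter from 92.4 to 98.5) and SNORD112 (100% and 88.9%, the latter from 70.8 to 97.6). The rule took 23 maternal and 23 paternal of 7904 genes in this pair, and 22 and 20 of 8208 in B6/CAST at E17.5. There Klf14 was maternal at 100% in both, Tssc4 at 81.2% (67.4 to 91.0) and 90.8% (82.7 to 95.9), and D7Ertd715e paternal at 96.4% (87.5 to 99.6) and 100%. The macrophage lysozyme Lyz2 was maternal at 71.4% (63.0 to 78.9) and 76.1% (61.2 to 87.4), and the granzyme Gzme at 100% and 75.7% (64.3 to 84.9). A SNORD113 entry stood at 90.6% (75.0 to 98.0) and 100% maternal. These values compare single libraries, and reads of overlapping Airn and Igf2r or of SNORD113 copies can be mixed, as can those of SNORD112, which lies within the span of Rian.

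At E13.5 the rule took 37 maternal and 20 paternal of 8433 genes, and 19 of the maternal genes were outside the joint fit. They included granzymes, the cytotoxic proteases of uterine natural killer cells. Gzmd stood at 100% and 98.5% (97.0 to 99.4) maternal reads in B6xCAST and CASTxB6, Gzmg at 100% in both, and Gzme at 99.0% (94.5 to 100) and 89.3% (85.3 to 92.5). Osteopontin (Spp1), a secreted phosphoprotein, stood at 98.6% (97.0 to 99.4) and 99.7% (99.0 to 99.9), the protease cathepsin K (Ctsk) at 97.7% (95 to 99.1) and 95% (90 to 98), 4930486L24Rik at 100% and 95.4% (91.7 to 97.8), and Asb4 at 83.9% (77.0 to 89.4) and 88.7% (83.6 to 92.7). The decidual prolactin Prl8a2, chosen after its values were seen, stood at 100% and 99.0% (94.3 to 100). RP23-407K8.3, at 84.6% (65.1 to 95.6) of 26 reads and 96.1% (95.7 to 96.4) of 9860 reads, is uncertain. The list of uterine natural killer cells and maternal leukocytes had a median maternal share of 100% and 98.5% at E13.5 (7 genes, 1064 and 1613 reads), and 61.7% to 76.5% over 3 to 5 genes in the libraries of E17.5. The decidual list ran from 47.0% to 61.6%. These medians are over different genes at each stage. Il2rb, a receptor chain of such cells, had 50.9% and 46.8% maternal reads at E13.5, and Gzme was still maternal at E17.5. At that stage Gzmg stood at 100% of 47 reads in CASTxB6 but fell short of 20 reads in B6xCAST. For Gzmg at E17.5 a strain effect therefore cannot be told from maternal origin. The granzymes are near copies of one another, and no change of these shares between stages was tested.

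Between E13.5 and E17.5 in B6/CAST, Hsd11b1, which regenerates active glucocorticoid, rose most, from 14.2 ± 1.48 to 524.6 ± 94.2 CPM (counts scaled to library size; SD, n = 2 per stage). Prl8a6, a prolactin family hormone of the spongiotrophoblast, rose from 100.8 ± 80.8 to 2560 ± 1839 CPM, the trophoblast cathepsin Cts6 from 574.9 ± 111 to 7131 ± 1557, the neutral amino acid transporter Slc1a4 from 47.0 ± 6.45 to 558.9 ± 40.6 and the TGF-beta binding protein Ltbp3 from 14.8 ± 0.0391 to 213.4 ± 98.6. The pepsinogen Pgc, Dram1 (autophagy), Itpka (an inositol kinase), Trank1 and Dcaf12l1 rose 9.17-fold, 8.87-fold, 7.46-fold, 8.82-fold and 8.82-fold. The embryonic globin Hbb-y fell from 4114 ± 1554 to 5.69 ± 2.16 CPM. Aldh1a3, an enzyme of retinoic acid synthesis, fell from 308.5 ± 313 to 22.1 ± 4.78, the mitotic kinase Cdc2a from 24.1 ± 1.91 to 2.36 ± 0.861, Nkain1 from 151.9 ± 29.3 to 15.5 ± 0.969 and the mitotic survivin gene Birc5 from 17.7 ± 4.31 to 2.26 ± 0.405. Prl6a1, AC125276.1, Wfdc2, AA467197 and Plac8 fell 8.98-fold, 8.09-fold, 7.70-fold, 6.72-fold and 5.51-fold. Some sizes rested on single libraries: without B6xCAST at E13.5 the log2 changes were -1.44 for Prl6a1, -1.88 for AC125276.1, -1.91 for AA467197, -1.45 for Plac8, -1.99 for Aldh1a3 and 3.97 for Pgc. Without CASTxB6 at E13.5 they were -3.94 for Prl6a1, -3.65 for AC125276.1, -3.06 for Plac8 and -4.59 for Aldh1a3, and without CASTxB6 at E17.5 -3.36 for AA467197. Prl8a6 ranged from 3.64 without CASTxB6 at E17.5 to 5.87 without CASTxB6 at E13.5.

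Of 8685 genes, 461 rose and 210 fell in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 371 and 149 of them at least 2-fold. Adjusted p of the named genes ran from 0.000629 for Hsd11b1 to 0.048 for Prl6a1. The libraries of the stages did not overlap for any of the 671 genes, nor for 57.4% of all genes, against 33.3% by chance. The spread within a stage includes the direction of the cross, and Prl8a6 differed between B6xCAST and CASTxB6 at E17.5 with 1260 and 3861 CPM. Without CASTxB6 at E13.5 there were 729 rises and 487 falls, where the lone library of that stage is assumed to vary like the others. Values are over SNPs, so CPM can be compared between libraries but not between genes.

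**Figure D4:**
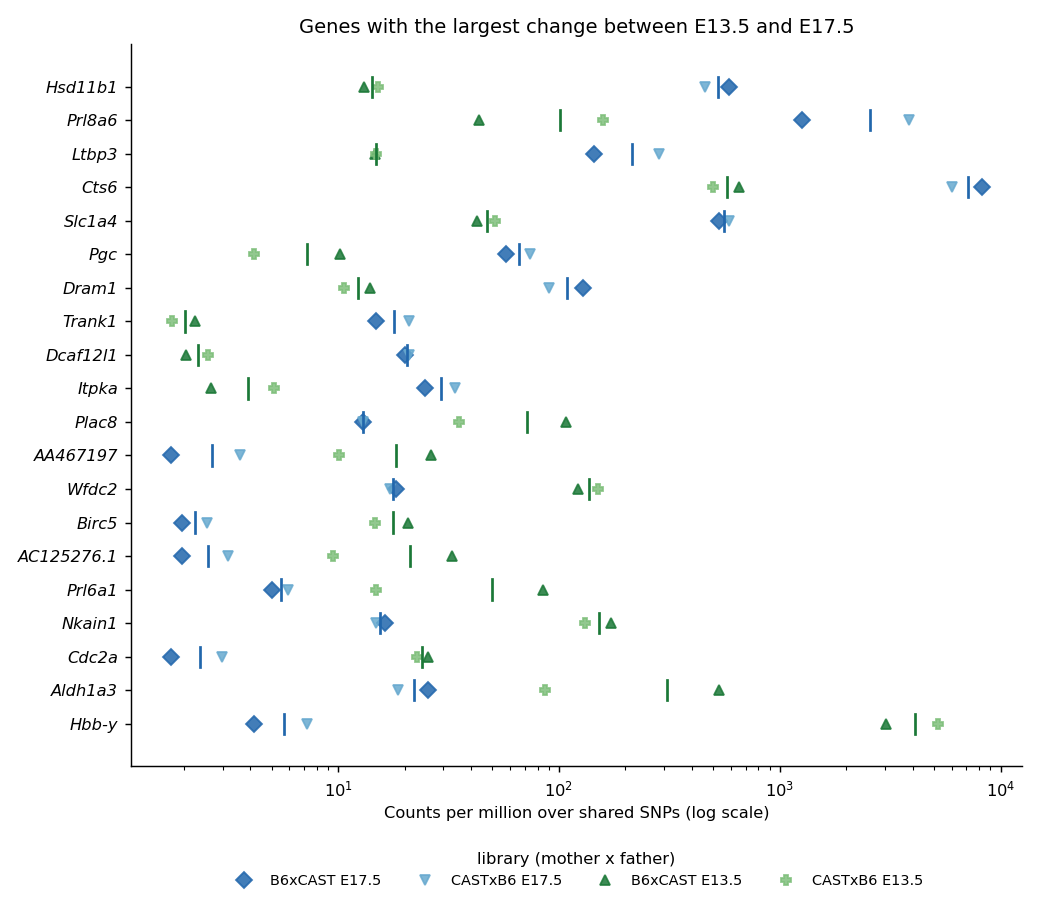
CPM over shared SNPs (log axis) of the 20 genes with the largest change, with 1 symbol per B6/CAST library and a vertical bar for the mean of each stage (green E13.5, blue E17.5; n = 2). Hsd11b1 moves from 14.2 to 524.6 and Hbb-y from 4114 to 5.69.

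Cell cycle genes fell together, 7 of 11 tested and all 11 adjusted over the list alone. The replication helicase genes Mcm3, Mcm2 and Mcm7 fell 5.10-fold, 3.77-fold and 2.92-fold and the ribonucleotide reductase Rrm2 2.59-fold, besides Cdc2a, Birc5 and the cyclin Ccna2 (2.47-fold). The list passed by camera (adjusted p = 7.63e-16) but not otherwise (adjusted p = 0.668 with an estimated correlation). Of 21 labyrinth and transport genes 6 rose and 1 fell, and 10 and 2 did so adjusted over the list alone. Risers were the amino acid transporter genes Slc38a2 and Slc7a5 (2.98-fold and 2.64-fold), the glucose transporter Slc2a1 (2.80-fold), the calcium genes S100g and Trpv6 (2.53-fold and 3.49-fold) and the transcription factor Tead4 (2.58-fold), while the lectin Lgals1 fell 2.52-fold. This list too passed only with the preset correlation (adjusted p = 0.00236, and adjusted p = 0.668 with an estimated correlation). Single libraries decided some members: Ccna2 was lost without CASTxB6 at E17.5 (log2 -1.18), S100g without B6xCAST at E13.5 (log2 1.18), Slc7a5 without either of these (log2 1.10 and 1.18), and Lgals1 without B6xCAST or CASTxB6 at E17.5 (log2 -1.30 and -1.36) or without B6xCAST at E13.5 (log2 -1.13).

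The remaining lists did not pass by camera at stage. In the spongiotrophoblast list Prl8a6 rose and Aldh1a3, the connexin Gjb5 (3.33-fold) and Prl6a1 fell, 4 of 13, with 2 rises and 5 falls adjusted over the list alone (adjusted p = 0.0529, camera). The decidual list (adjusted p = 0.0529) had 3 rises of 13, the growth factor carrier Igfbp3 (4.97-fold) and the smooth muscle genes Myh11 (2.60-fold) and Tagln (2.41-fold), and 6 rises and 1 fall adjusted over the list alone. Hypoxia and glycolysis (adjusted p = 0.0529) had 2 rises of 12, hexokinase Hk2 (3.44-fold) and Slc2a1, and 4 rises and 1 fall adjusted over the list alone. In extracellular matrix elastin (Eln, 4.90-fold), Timp3 (3.45-fold) and Bgn (1.83-fold) rose, 3 of 21, with 1 fall more adjusted over the list alone, and its median log2 was -0.04 although the test pointed up. Of trophoblast giant cell genes (11) the cathepsin Ctsq rose 7.14-fold and Plac1 fell 4.48-fold, with 2 of each adjusted over the list alone; the median log2 was -0.18 while the test pointed up. Plvap (2.38-fold) was the 1 of 13 endothelial genes and Bgn the 1 of 12 escape genes that rose, with 1, and 2 rises and 1 fall, adjusted over the list alone.

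Of known paternal genes (20) Plagl1 (2.42-fold) and Zdbf2 (2.69-fold) rose and Ndn (2.53-fold) fell, with 5 rises and 1 fall adjusted over the list alone. Of known maternal genes (23) Grb10 rose 2.29-fold, also adjusted over the list alone. Yolk sac (17), erythroid (4), interferon response (15) and genes reported as maternal (9) had 0 past edgeR's threshold at either adjustment, as with Afp at 5293 ± 2605 and 7527 ± 3590 CPM (SD, n = 2), which turned without B6xCAST at E17.5 (log2 -0.09). Uterine natural killer genes (4) had 0 over all genes by edgeR and 3 falls and 1 rise adjusted over the list alone, while DESeq2 passed Gzme (log2 -1.28) and Il2rb (-0.95) as falls and Lyz2 (2.04) as a rise. With a term for cross direction edgeR passed Gzme (-1.26), Gzmg (-1.95) and Lyz2 (1.89). Without CASTxB6 at E17.5 Gzme (-1.86), Gzmg (-3.38), Il2rb (-1.37) and Lyz2 (2.62) passed, without B6xCAST at E13.5 Gzme (-1.74), Gzmg (-2.22) and Lyz2 (2.14), and without CASTxB6 at E13.5 Gzmg (-1.19), Il2rb (-1.17) and Lyz2 (1.92). Without B6xCAST at E17.5 Gzmg (-1.06) and Lyz2 (1.04) did not. The embryonic globin list had 1 tested member, Hbb-y. Of the genes named for these lists, Myh11, Tagln and Bgn were lost without B6xCAST at E17.5 (log2 1.05, 0.87 and 0.73), Plvap without CASTxB6 at E17.5 (0.82), Plagl1 without either B6xCAST library (1.06 and 1.04), and Ndn without each library in turn (-1.24 to -1.44). With a term for cross direction Ndn (-1.34) and Bgn (0.87) did not pass either.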

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

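The tests of the Peg10 pattern and the counts of other assignments were chosen after the result was seen. Of 45 sets of 6 library shares examined, 10 had a library far from the others. Chance would give about 1 in 20 only for independent, normally distributed values. Some of these shares are tied because small non-reference shares are mostly not listed, and strain effects move others by cross direction. That rate therefore does not apply here, and whether 10 of 45 is more than chance cannot be told.

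Peg10 had 11.3% maternal reads in CASTxB6 at E17.5, against 0% to 0.599% in the other libraries, and its neighbour Sgce 17.7% against 6.13% to 9.07%. RNA of another placenta could bring maternal reads to other paternally read genes as well, and RNA of the mother only to those that maternal tissue expresses. In this library 7 other paternally read genes had a median maternal share of 0%, although CAST shares of a few percent are mostly listed at 0. RNA of the mother is not excluded by this, since expression in maternal tissue was not measured. A wrong genotype at single SNPs is argued against by 10 of 11 Peg10 SNPs with over 5% CAST reads, while 0 of 11 had them in CASTxB6 at E13.5. Partial maternal expression of this domain in this placenta may be a biological explanation, but with 1 library of this cross and stage it stays open.

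Slc38a4 had 24.1% maternal reads in B6xCAST at E13.5 (0% to 7.92% elsewhere), and Zrsr1 13.5% in the same library (0% to 3.57%). Dlk1 had 2.23% there (0% to 0.803%). Rian had 93.5% maternal reads in PWDxAKR, against 97.8% to 100% elsewhere. Smoc1 had 46.1% in PWDxAKR (22.5% to 28.1%), and Trappc9 64.1% (51.6% to 55.4%). The entry mmu-mir-431, whose SNPs lie within the span of Rtl1 and whose reads may be those of Rtl1, had 2.44% in B6xCAST at E17.5 (0% to 0.446%). Mest had 0.301% in AKRxPWD and was listed at 0 in the others, of which the B6/CAST libraries held only 32 to 40 reads each.

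Other assignments of mother and father within the libraries were counted for the autosomal parental calls. The real assignment gave 59 genes and the highest of the others 1, so that 1 of 30 assignments, the real one, gave as many. This argues against chance only for the calls as a whole. In the other assignments the bias of imprinted and X-linked genes adds to the spread, which by itself lowers the number of calls. Whether weaker calls among the 59 are chance cannot be told from these counts. For the strain term in B6/CAST the real assignment gave 1898 genes and the highest other 0, but 8 assignments, of which 1 gave as many, are too few for a share under 0.05.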

How the results depend on the processing

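The values with non-reference alleles listed at 0 set to 2% of coverage, with the 4 libraries of E17.5 only, and without X-linked and parentally biased genes were chosen after seeing the data. Of the alternative values for the main results, 97 kept the result, 15 moved it by more than 1.5-fold or to or from 0, and 6 lost significance. Autosomal maternal calls fell from 37 to 18 with a 2-fold minimum, and ranged from 29 to 35 without single libraries, paternal calls from 22 to 24. With E17.5 libraries only, 54 of the 59 parental calls remained, and with B6/CAST libraries only 50. Strain calls in B6/CAST were 1206 with DESeq2 and 1195 to 1588 without single libraries. In AKR/PWD they were 510 with DESeq2 and 46 to 1058 without single libraries, where leaving out either AKR/PWD library leaves 1 library for the term. Without X-linked and parentally biased genes there were 1800 and 855 strain calls. Differences in bias between strain pairs rose from 0 to 3 with all SNPs summed, 2 with TMM, 3 with median-of-ratios and 3 with DESeq2; the cause was not tested. The X-linked mean ranged from 96.3% to 97.3% without single libraries, and 5 libraries cannot give p under 0.05. Requiring 90% in the rule of size left 24 genes in B6/CAST at E17.5 and 32 at E13.5, by construction. Stage calls ranged from 618 to 1216 without single libraries, and 623 of 671 genes remained in the set of 1216; the cause was not tested. With an estimated correlation 0 of the 2 stage lists passed. The strain terms of Igf2 (-0.40), Rhox6 (-0.16) and Rhox9 (-0.11) reversed with zeros at 2% of coverage, which by construction adds CAST reads. That of Zfp36l3 in AKR/PWD ranged from -0.52 to 6.00 without single libraries; the cause was not tested. For named genes called in the main fit, the parent term kept its call in 723 values and lost it in 2, the stage term in 403 and 19, the AKR/PWD strain term in 184 and 20, with 1 reversed, and the B6/CAST strain term in 217 and 0, with 3 reversed. The 2 parent losses were of Phf17. The parent counts leave out calls such as Nap1l4, Pon2 and Angpt2, which were less stable. Nap1l4 was lost with DESeq2, Angpt2 with DESeq2 and with all SNPs summed, and each of the 3 without some single libraries. For named genes not called, the parent term gained a call in 10 values and the stage term in 47, while 276 and 457 stayed uncalled, 19 and 27 of them with the sign turned. Removal of possibly wrong genotypes took out 0 SNPs and tests nothing. Depth limits genes under 20 reads, and small non-reference shares are not seen. By replicate number no paired analysis was possible because groups of 1 library share fewer than 2 numbers. Alleles were paired within libraries in the parental fit, and pairing the stages by cross direction gave 582 stage calls, 522 of them shared.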

Other observations

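Gene families and all tests in this part were chosen after the result was seen.

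Some solute carriers, which move nutrients across membranes, rose from E13.5 to E17.5. Of 149 solute carrier genes tested in B6/CAST, 17 rose and 2 fell (12.8%, against 7.73% of all genes past the threshold, edgeR). The magnesium transporter Slc41a1 rose from 66.8 ± 11.5 to 432.9 ± 36.7 CPM (counts scaled to library size; SD, n = 2), the phosphate transporter Slc20a1 from 207.0 ± 4.82 to 786.1 ± 82.8, the vitamin transporter Slc5a6 from 108.2 ± 28 to 394.1 ± 88.9, and the amino acid transporters Slc7a8 and Slc7a1 from 202.6 ± 127 to 1032 ± 415 and from 934.2 ± 167 to 2673 ± 212. The zinc transporter Slc39a6 fell 2.33-fold and the mitochondrial carrier Slc25a10 fell 1.76-fold. No enrichment was tested.

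Of 15 serpins, 4 fell and 0 rose, all protease inhibitor genes of the Serpinb9 cluster. Serpinb9e fell from 934.6 ± 211 to 265.1 ± 54.6 CPM (SD, n = 2), Serpinb9c from 467.1 ± 64.8 to 148.1 ± 28.7, Serpinb9g from 238.8 ± 94.1 to 56.7 ± 6.32 and Serpinb9d from 44.8 ± 2.74 to 15.8 ± 4.64. For the strain term, 75% of 8 prolactin genes, 72.2% of 18 Ceacam and Psg genes, 60% of 10 serpins and 53.8% of 13 cathepsins were past the B6/CAST threshold (edgeR), against 27.4% of 6652 autosomal genes. These differences in share were not tested, and many members are near copies, so their allele counts are uncertain.

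Calls of moderate maternal bias clustered around imprinted genes, but most of the 483 other tested autosomal genes within 5 Mb had none. Of 22 maternal calls outside the known list, SNORD entries aside, 16 lay within 5 Mb of a called known imprinted gene, against a mean of 1.62 and a highest value of 7 in 10000 random draws of as many autosomal genes (95th percentile 4). Among the 16, Pde10a, Slc22a3, Ppp1r9a, Pon2, Casd1 and Nap1l4 were on the list of genes already reported as maternal in placenta. No count was made without them. The draws took no account of read depth or of bias shared by neighbouring genes. RNA of maternal tissue, such as decidua, would not follow position, so for these 16 genes as a set, not for each, it is argued against as the sole source. Without AKRxPWD 10 of 15 such calls lay within 5 Mb, and without PWDxAKR 10 of 14 (highest draw 6 for each), and 9 of the 16 were called in either case. These 2 counts exceed the draws as well, but they are not separate evidence. The AKR/PWD library left is taken up by its strain term, so both rest on the 4 B6/CAST libraries. Weaker maternal expression around imprinted genes may be a hypothesis. For the 6 others (Arid1b, Cbx7, Angpt2, Ctla2a, Cat and Hbb-b2) the maternal share at E13.5 minus that at E17.5 had a median of 3.3 percentage points (-0.24 to 15.3), and maternal RNA stays open. Granzyme reads were maternal at E13.5, but those of Il2rb were not (50.9% and 46.8%), so the stages are no clean contrast of maternal RNA.

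Most of the 9 X-linked genes without parental bias were higher from CAST, Fndc3c1 excepted. Their median CAST share averaged 72.9% over the B6/CAST libraries (60.4% to 83.4%), which argues against mapping to the B6 reference as the cause, and 8 of 9 were called higher from CAST, against a mean of 1.14 and a highest value of 5 in draws of autosomal genes, which argues against separate strain effects of single genes. Maternal shares with CAST mothers exceeded those with B6 mothers by a median of 40.1 points (-11.5 to 60.7), and by a median of 6.91 for 9 listed escape genes (highest 51.3). Of these escape genes, Bgn and Sh3bgrl are themselves among the 9 genes and differ as much, so the comparison decides nothing, and a preference for an active CAST X in cells with random X inactivation stays open. In AKR/PWD the median AKR share of these genes was 52.0% (40.5% to 58.5%), and 4 libraries cannot give an exact p under 0.125.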
